A study of Mus musculus with 24 samples.

How the data were processed

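Illumina bead arrays had been hybridised with biotin-labelled, amplified cRNA from Trizol-extracted RNA of the cerebellum, frontal cortex and hippocampus of Srr mutant and wild-type mice, 4 arrays for each of the 6 groups. Tissue came from mice killed by cervical dislocation and was dissected and frozen. Which slide carried which array is not given in the sources used here, so no slide term was fitted.

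The authors processed the arrays with lumi 1.6.2 in R 2.7.2 and deposited a value table of log2 expression values, 1 per probe and array. The exact transformation is not given in the sources used here. Checked against the bead intensities, the deposited values follow log2 intensity with a slope of 1.03 at the bright end and 0.199 at the dim end, so differences between dim probes are compressed. Columns of a region had nearly equal distributions (sorted values within 0.03, with the extremes at both ends left out). Their highest values differed more, such as 14.57 to 14.87 in the cerebellum. Column medians were 7.53 in the cerebellum, 7.83 in the frontal cortex and 7.73 in the hippocampus. The authors also deposited bead-level files with the intensity of each bead, already background-subtracted, for 26821 bead types. Bead codes could not be paired with genes from the sources used here, so every named gene comes from the value table, and the bead files only count bead types. Where an intensity is given for Srr, it was mapped from the deposited value to the bead intensity at the same quantile within a region, and was not read from a bead. This departs from the plan made before the data were examined, which took bead intensities for the main values.

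The table held 25697 probes, of which 23978 carried 1 gene symbol and 1719 none. Symbols were matched to the reference gene table by gene identifier. The values of all 24 arrays were quantile-normalised together. A probe was tested when its value was above the 40th percentile of its array on at least 4 arrays, which left 17512 probes of 12821 genes. limma 3.58.1 in R 4.3.3 fitted 1 mean per group (18 residual degrees of freedom) with empirical Bayes moderation and a trend in the prior variance. Benjamini-Hochberg adjustment ran over the 17512 probes, with a threshold of 0.05, and a gene counted once when any of its probes passed. Comparisons were mutant against wild type in each region, their mean over the 3 regions, the interaction of genotype and region (an F test, and 3 tests between pairs of regions), and the 3 pairs of regions within wild type. Other tools were statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Median within-group SD was 0.0848 in the cerebellum, 0.0615 in the frontal cortex and 0.0662 in the hippocampus. The fit shared 1 residual variance per probe over the 3 regions, and each number of probes that chance gives assumes this.

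Before the data were examined, 30 gene lists, the rule for named genes, the threshold, the model, the filter and most alternatives were fixed. For each mutant comparison the rule names Srr, the 10 largest rises and the 10 largest falls past the threshold, or, where fewer than 10 pass, those that pass and the next by p up to 10 (given as not past the test), with up to 4 members per list by smallest p. For pairs of regions it names the 5 largest each way and up to 4 members of each regional or cell-type list, and for the interaction the 10 smallest p. Ecrg4 and Igf2, and any other gene named outside the rule, were chosen after their values were seen. The lists cover D-serine, L-serine and glycine metabolism and transport, NMDA receptor subunits, AMPA, kainate, delta and metabotropic glutamate receptors, glutamate metabolism and transport, postsynaptic density scaffolds and serine racemase partners, calcium, calcineurin and CREB signalling, GABA synthesis, receptors and interneuron markers, schizophrenia candidate genes, monoamine and acetylcholine signalling, activity-regulated immediate early genes, and synaptic vesicle release machinery. They also cover markers of oligodendrocytes and myelin, astrocytes, microglia and macrophages, vessels, choroid plexus, blood, meninges and fibroblasts, and of neurons of the cerebellum, neocortex, hippocampus, striatum, thalamus and hypothalamus, and olfactory bulb. The rest are oxidative phosphorylation subunits, cytosolic ribosomal proteins, heat shock, unfolded protein and amino acid response genes, glucocorticoid-responsive genes, circadian clock genes and genes near Srr on its chromosome.

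Lists were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. fry tests whether a list's genes move on balance in 1 direction and does not compare them with other genes. List scores (mean of the genes' values minus the wild-type mean of the region) were compared by exact permutation tests.

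The fit was tested on simulated data with normal noise of each probe's residual SD around the wild-type means, with 200 of the 17512 probes changed. A change of 0.3 was recovered for 71.6% of probes in the cerebellum and 67.2% in the frontal cortex and the hippocampus, a change of 0.6 for 98.5%, 97% and 95.5%, with 8, 7 and 11 false calls. A change of 0.3 in every region was recovered for 94% in the mean, with 14 false calls, and a change of 0.6 in the hippocampus alone for 91.5% in the interaction, with 11 false calls. A shifted list was called by camera and by fry, and 0 of the 29 others were. The noise was drawn independently for each probe, while estimated correlations within the real lists reached 0.738. The simulation therefore cannot show how often correlated lists are called falsely. A probe also had the same SD in every group, while the median SD of the real arrays differed between regions (0.0848, 0.0615 and 0.0662). The false calls of the simulation are therefore no error rate for the real comparisons.

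Whether the replicate numbers pair mutants with wild types was checked by the correlation of deviations from the group means. In the frontal cortex all 4 same-numbered pairs were over 0.1 (0.239, 0.149, 0.151 and 0.179), while in the cerebellum 1 of 4 was -0.274 and in the hippocampus 3 of 4 were below 0. The labels name no shared animal, litter or day.

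Alternatives were other scalings (as deposited, median, cyclic loess, within a region), no filter and a stricter one, other thresholds, a fit to the 8 arrays of a comparison alone, no trend, a robust prior, array weights, the replicate number within a region as a fixed block, genotype and number as a random block of 1 animal, other summaries of the bead files, and leaving out each array in turn. Chosen after seeing the data were bead intensities as written in the plan, normexp with an offset of 50 on them, the log2 intensity scale by quantiles, leaving out both animals numbered 3, the D-serine list score without Srr, and the choroid plexus score as a covariate. Animals numbered 3 stands for all arrays with replicate number 3, which the labels do not tie to 1 animal.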

Results

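Transcript levels were measured with Illumina bead arrays in the cerebellum, the frontal cortex and the hippocampus of mice carrying a stop mutation in Srr and of wild-type mice. Srr encodes serine racemase, the enzyme that makes D-serine, a co-agonist of the NMDA receptor. Per the labels the mice were males of 9 weeks on a C57BL/6 background, and each of the 6 groups of region and genotype held 4 arrays, 24 in all. The arrays held between 989929 and 1069789 beads each, with a median of 38.5 beads per bead type. Cerebellar arrays were dimmer than those of the other regions, with a 95th percentile of bead-type intensity of 1346 ± 72.5 (SD, n = 8), against 2465 ± 269 in the frontal cortex and 2437 ± 533 in the hippocampus. Arrays of 1 group correlated at 0.983 to 0.997 across probes, which are not independent replicates. The number of arrays limits the precision of each value.

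Srr, the mutated gene, fell in the mutants in the frontal cortex and the hippocampus. On the log2-like scale of the deposited values, it fell less in the cerebellum than in either. In the frontal cortex its level on the log2-like scale of the deposited values was 8.77 ± 0.12 in mutants and 9.46 ± 0.26 in wild type (SD, n = 4 each), a difference of -0.70 ± 0.10 (SE, limma adjusted p = 0.00175). In the hippocampus the level was 8.77 ± 0.10 against 9.64 ± 0.12, a difference of -0.86 ± 0.10 (adjusted p = 2.87e-05). In the cerebellum it was 8.42 ± 0.12 against 8.63 ± 0.07, and the difference of -0.21 ± 0.10 did not pass the test (adjusted p = 0.474). As the mean of the 3 regions, Srr fell by 0.59 ± 0.06 (adjusted p = 8.31e-07). The highest mutant array lay below the lowest wild-type array in the frontal cortex (8.93 and 9.09) and in the hippocampus (8.92 and 9.46), and overlapped it in the cerebellum (8.57 and 8.54). The mutant effect in the cerebellum differed from that in the hippocampus by 0.65 (limma adjusted p = 0.00017 over the 3 pairs of regions) and from that in the frontal cortex by 0.48 (adjusted p = 0.00216). The effects in the frontal cortex and the hippocampus differed by 0.17 (limma adjusted p = 0.23). Over all genes, limma's test of any difference between regions gave an adjusted p of 0.212 for Srr. Mapped from the deposited values to bead intensity by quantiles within a region, less a background taken as the 25th percentile of bead types, the mutant level was 70.9% of wild type in the cerebellum, 48.5% in the frontal cortex and 41.5% in the hippocampus. A fit to the 8 frontal cortex arrays alone left the difference of -0.70 with an adjusted p of 0.477. Srr was measured by 1 probe, whose place relative to the stop codon is not given in the sources used here, so the values describe transcript level and not the length of the product.

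**Figure D1:**
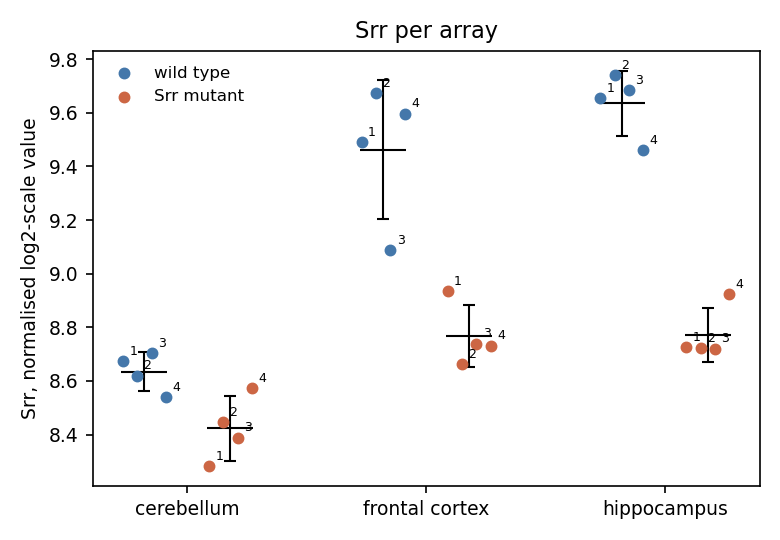
Level of Srr (log2-like scale) in each of the 24 arrays by region and genotype, with points for arrays, numbered by replicate, and bars for the group mean and SD. Mutant and wild-type arrays lay apart in the frontal cortex and the hippocampus and overlapped in the cerebellum (8.57 and 8.54).

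Of 23 measured genes of D-serine, L-serine and glycine metabolism and transport, Srr was the 1 gene that fell in the frontal cortex and in the hippocampus, over all genes and adjusted over the list alone. As the mean of the regions, adjusted over the list alone, Slc38a5, a glutamine and glycine transporter, passed too (-0.20), so 2 genes passed over the list alone and 1 over all genes. The list's median difference was -0.00651 in the cerebellum, -0.0177 in the frontal cortex and -0.0125 in the hippocampus (camera adjusted p = 0.357, 0.194 and 0.344). The list's score differed by -0.0359, -0.0329 and -0.0454 (exact two-sided permutation p = 0.171, 0.143 and 0.0286, the last 0.428 adjusted over the 30 lists), with 2, 3 and 4 mutants below the lowest wild type. Without Srr, a test chosen after the data were seen, the score of the other 22 genes differed by -0.028, -0.00279 and -0.00823 (exact permutation p = 0.257, 0.857 and 0.6). The 4 measured NMDA receptor subunits, Grin2a, Grin2b, Grin2c and Grin3b, had medians of -0.00292, 0.0104 and 0.0038 (camera adjusted p = 0.91, 0.522 and 0.755), and 0 of them passed limma's test in any region. Of 43 measured genes that neighbour Srr on its chromosome, 0 passed over all genes, and adjusted over the list alone 1 did, Slc43a2, an amino acid transporter, in the cerebellum (0.11). The medians of these neighbours were 0.0342, -0.00813 and 0.0152 (camera adjusted p = 0.109, 0.522 and 0.347).

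In the cerebellum 6 genes passed in the reported fit. No gene passed with the values as deposited, with the other scalings, with array weights or from the 8 cerebellar arrays alone. In 14 of 35 splits of these arrays, the real one included, as many genes passed. In the reported fit, the mutants had higher levels of Fcsk, the kinase that salvages free fucose, of Fut8, which adds the core fucose to N-glycans, and of Wipi2, a protein of early autophagosome formation. They had lower levels of Rbfox1, a neuronal splicing regulator, of Svep1, a secreted matrix protein, and of Tm6sf2, a membrane protein of lipid export. Fcsk rose by 0.33 (9.33 ± 0.10 in mutants and 8.99 ± 0.04 in wild type, SD, n = 4, limma adjusted p = 0.0341), Wipi2 by 0.26 (7.96 ± 0.07 and 7.70 ± 0.04; 0.00764) and Fut8 by 0.19 (7.93 ± 0.03 and 7.74 ± 0.04; 0.00946). Svep1 fell by 0.17 (8.23 ± 0.03 and 8.39 ± 0.05; 0.0446), Rbfox1 by 0.16 (7.59 ± 0.04 and 7.75 ± 0.07; 0.0263) and Tm6sf2 by 0.12 (7.61 ± 0.02 and 7.73 ± 0.02; 0.0263). The mutant levels of Rbfox1 and Tm6sf2 lay at the 35.3 and 39.4 percentile, under the filter's 40th, so that their falls are lower bounds. Leaving out 1 array, Wipi2 and Fut8 kept their call in all 24 fits, while Svep1 lost it in 17, Fcsk in 9, Rbfox1 in 3 and Tm6sf2 in 2, each at an adjusted p of at most 0.0866. Only 8 of these fits left out a cerebellar array. Of the probes of these genes, 2 of 3 for Wipi2 and 1 of 2 for Rbfox1 had the sign given here. Next in order, and not past the test, stood Sh3pxd2a (-0.13), Plek2 (-0.13), Mgst1 (-0.25) and 6330403K07Rik (-0.41), each with an adjusted p of 0.0711. The mutant levels of Sh3pxd2a and Plek2 lay at the 21.2 and 39.7 percentile, where differences are compressed, but no bound follows for a difference that did not pass.

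By gene group in the cerebellum, cytosolic ribosomal proteins had a median difference of -0.108 with 5 of 28 genes above 0. Examples were Rpl23 (-0.26), Rpl10 (-0.24) and Rpl5 (-0.21). Subunits of oxidative phosphorylation had a median of -0.0776 with 6 of 39 above 0, such as Atp5j (-0.26) and Uqcrc1 (-0.18). Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, had a median of -0.208 with 0 of 14 above 0. Each of these 3 lists had a camera adjusted p of 0.0372 and an adjusted p = 0.973 with an estimated correlation, and 0 of their genes passed limma's test, over all genes or adjusted over the list alone. The choroid plexus median was -0.0365 without wild type 2 (adjusted p = 0.688), and -0.317, -0.333 and -0.341 without mutant 3, wild type 1 and wild type 3. That of ribosomal proteins was -0.0459 and -0.056 without mutants 2 and 3 (0.702 and 0.4), and -0.183 and -0.181 without mutant 1 and wild type 3. That of oxidative phosphorylation was -0.0347 and -0.042 without mutants 2 and 3 (0.702 and 0.792), and -0.169, -0.127 and -0.159 without mutant 1, mutant 4 and wild type 3. Adjusted over the list alone, 2 genes of synaptic vesicle release passed, Rims1 (0.22) and Sv2a (0.31), and Dusp1 of the immediate early genes, while over all genes 0 did. Of the 6 called genes 3 were higher, and 1760 probes had an unadjusted p under 0.05, where chance gives 876. That 876 assumes the variance shared over regions, while the cerebellum had the largest median within-group SD (0.0848, against 0.0615 and 0.0662). The excess is therefore no count of mutant effects. The count was 43 genes without mutant array 1, 34 without wild-type array 3 and 16 without mutant array 4. It was 0 with the values as deposited, with median scaling, cyclic loess or quantile scaling within a region, with array weights, or from the 8 cerebellar arrays alone. Fitted with the choroid plexus score as a covariate, 2 genes passed, and on the log2 intensity scale 1. After a stricter filter on dim probes 3 passed, and 3 with the replicate number as a fixed block. Without both animals numbered 3 there were 10, of which Fut8, Rbfox1 and Wipi2 are among the 6, so that Fcsk, Svep1 and Tm6sf2 lost their call.

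In the frontal cortex, Srr was the 1 gene that passed the test. Npas4, a transcription factor switched on by neuronal activity, had a difference of -0.49 (8.30 ± 0.31 in mutants and 8.78 ± 0.22 in wild type, SD, n = 4, adjusted p = 1), with 1 of its 2 probes of that sign. Other genes with small unadjusted p had an adjusted p of 1 too, among them Vxn (-0.29), Trhr, the thyrotropin-releasing hormone receptor (-0.21), Nup88, of the nuclear pore (-0.21), Oxsr1 (-0.13) and Doc2a, a calcium sensor of transmitter release (0.12). H2bu2 (0.12), Vmn2r28 (0.08) and Ldah complete the 10 named here. The wild-type level of Vmn2r28 lay at the 31.1 percentile, where differences are compressed. Ldah had 0.25 with its probe of smallest p and -0.07 with another. In all, 416 probes had an unadjusted p under 0.05, where chance gives 876 under the variance shared over regions. The frontal cortex had the smallest median within-group SD (0.0615), so the shortfall is no measure of the mutant effect. The count was 2 genes without mutant array 1 or without wild-type array 4, and 0 from the 8 arrays of the region alone.

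Gene groups in the frontal cortex had small median differences that camera called and an estimated correlation did not. Subunits of oxidative phosphorylation had a median of 0.121 with 36 of 39 genes above 0, such as Ndufb8 (0.24), Sdhd (0.24) and Ndufv2 (0.19). Camera gave an adjusted p of 4.01e-06, and adjusted p = 0.631 with an estimated correlation. Cytosolic ribosomal proteins had a median of 0.1 with 23 of 28 above 0 (camera 8.99e-04, adjusted p = 0.65 with an estimated correlation). Immediate early genes had a median of -0.0531 with 7 of 25 above 0, such as Egr1 (-0.41) and Junb (-0.37) (camera 8.99e-04, adjusted p = 0.631 with an estimated correlation). Adjusted over the list alone, 1 gene, Npas4, passed, and 0 did over all genes. Medians were 0.0743 for microglia and macrophage markers, 0.0848 for striatal neuron markers, -0.0333 for calcium, calcineurin and CREB signalling and -0.0328 for AMPA, kainate, delta and metabotropic glutamate receptors (camera 0.0188, 0.0043, 0.0188 and 0.0476). Each of these 4 had an adjusted p = 0.631 with an estimated correlation. Glucocorticoid-responsive genes had a median of 0.116 (camera 0.0466, adjusted p = 0.654 with an estimated correlation). Their score had an exact permutation p of 0.514, with 1 mutant above the highest wild type, and with the replicate number as a block camera gave an adjusted p of 0.0562. Without mutant array 2 their median was 0.0309 (adjusted p = 0.881). The median of the immediate early genes was -0.0224 without mutant array 4 (adjusted p = 0.407) and -0.00993 without wild-type array 2 (0.148). It was -0.0111, -0.122 and -0.0921 without mutants 1, 2 and 3 and -0.0938 without wild type 4, with the call kept. The median of oxidative phosphorylation was 0.0764 and 0.072 without mutants 3 and 4, and that of ribosomal proteins 0.153 and 0.0549 without mutants 2 and 3, with the calls kept. Striatal markers ranged from 0.0289 without wild type 2 (adjusted p = 0.271) to 0.167 without wild type 4, with 0.131 without mutant 1 and 0.0502 without mutant 4. Calcium genes ranged from -0.0583 without wild type 3 to -0.019 without wild type 4 (0.221), with -0.0504 without wild type 1. Microglia markers were at 0.0336 without mutant 4 (0.334) and 0.0483 without mutant 3, and glutamate receptors at -0.0212 without wild type 4 (0.226). The beta-globin gene Hbb-bt, a marker of blood, had a difference of 0.70, past the test adjusted over the list alone and not over all genes, where 0 blood markers passed.

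In the hippocampus, genes of the choroid plexus rose together in the mutants, and most markers of hippocampal neurons lay below wild type. The choroid plexus genes include Clic6, a chloride channel protein, Kl, the anti-ageing hormone klotho, and Sostdc1, a secreted BMP antagonist. They also include Folr1, the folate carrier into cerebrospinal fluid, Aqp1, a water channel, Cldn2, a tight junction protein, Kcne2, a potassium channel subunit, and Otx2, the transcription factor that specifies this epithelium. Clic6 rose by 2.37 (10.13 ± 1.66 in mutants and 7.76 ± 0.03 in wild type, SD, n = 4, limma adjusted p = 0.0173), Kl by 1.38 (9.70 ± 0.99 and 8.32 ± 0.13; 0.0283), Sostdc1 by 1.33 (9.34 ± 0.92 and 8.02 ± 0.06; 0.0283) and Otx2 by 1.10 (8.76 ± 0.80 and 7.66 ± 0.03; 0.0173). Folr1 rose by 1.10 (adjusted p = 0.0231), Kcne2 by 1.05 (0.0451) and Cldn2 by 0.98 (0.0113). The wild-type levels of Folr1 and Cldn2 lay at the 38.6 and 30.5 percentile, under the 40th percentile used as the filter, so that their differences are lower bounds. That of Kcne2 lay at the 41 percentile, and Kcne2 lost its call in 19 of 24 fits without 1 array, at an adjusted p of up to 0.375. The rise stood in 3 of the 4 mutant arrays: Clic6 was at 11.10, 11.10 and 10.66 in mutants 2, 3 and 4 and at 7.67 in mutant 1, below its wild-type mean of 7.76. Ttr, the most abundant transcript of the choroid plexus, was at 14.96 in mutants 2, 3 and 4 and at 9.73 in mutant 1, against 10.48 ± 0.40 in wild type, and did not pass the test (adjusted p = 0.763). Since 14.96 is the top of the scale, the levels in mutants 2, 3 and 4, and with them the difference of 3.17, may be understated.

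All 14 measured choroid plexus markers lay above 0 in the hippocampus, with a median difference of 1.08 (camera adjusted p = 1.72e-37, adjusted p = 0.0135 with an estimated correlation, fry adjusted p = 0.00985). Of them 10 rose over all genes and 13 adjusted over the list alone, where Tmem72 (0.02) was the exception. The score of the list was above the highest wild-type score in 3 mutant arrays and below the lowest in mutant 1, so that the score difference of 1.25 had an exact two-sided permutation p of 0.143 (adjusted over the 30 lists 0.428), where the smallest possible was 0.0286. Sulf1, an editor of heparan sulfate (0.99, adjusted p = 0.0162), Slc4a2, an anion exchanger (0.84; 0.0113), and Cd59a, an inhibitor of complement (0.97; 0.0283), are outside the list and rose too. Cd59a was higher in each of the 4 mutant arrays (lowest 9.30) than in each wild-type array (highest 8.92).

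**Figure D2:**
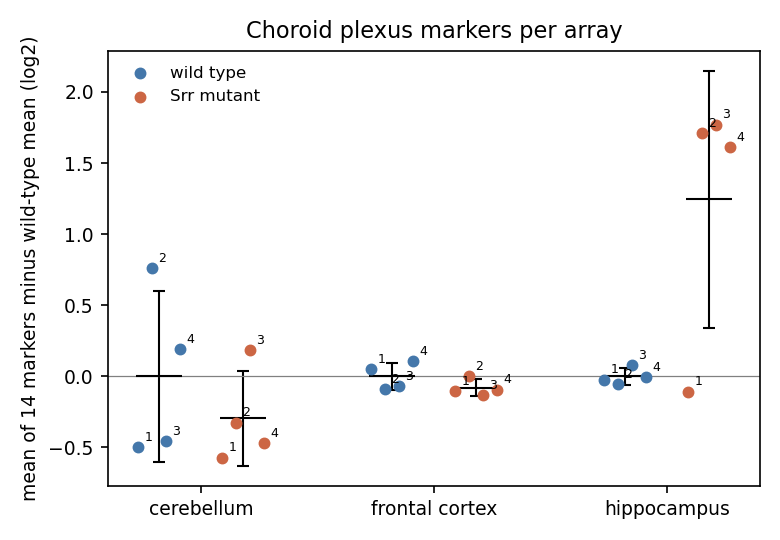
Score of the choroid plexus marker list (mean of its 14 genes minus the wild-type mean of the region, log2) in each array by region and genotype, with points for arrays, numbered by replicate, and bars for the group mean and SD. Hippocampal mutants 2, 3 and 4 lay at 1.71, 1.77 and 1.61, and mutant 1 at -0.108, beside a highest wild-type score of 0.0807.

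Of 13 measured hippocampal neuron markers, 3 lay above 0 in the mutant hippocampus and the median difference was -0.0892 (camera adjusted p = 0.00204, adjusted p = 0.0183 with an estimated correlation, fry adjusted p = 0.00985). The score of this list differed by -0.0819 (exact two-sided permutation p = 0.0571, adjusted over the 30 lists 0.428). In the same arrays the score of striatal neuron markers lay higher by 0.0551 with all 4 mutants above every wild type (exact permutation p = 0.0286, adjusted 0.428), while camera gave that list an adjusted p of 0.344. The median of the hippocampal neuron markers was -0.0499 without wild-type array 2, with the call of camera at the preset correlation kept (adjusted p = 0.00261). Lefty1, a TGF-beta family antagonist, fell by 0.22 (8.42 ± 0.07 in mutants and 8.63 ± 0.09 in wild type, SD, n = 4, adjusted p = 0.0323) and was the 1 member past the test over all genes. These are the same arrays in which the choroid plexus list had a median of 1.08. Adjusted over the list alone 3 members fell: Lefty1, Spink8, a secreted protease inhibitor of pyramidal cells (-0.22), and Iyd (-0.09). The other falls were Srr, Fam171a1 (fell by 0.56; 7.95 ± 0.35 and 8.51 ± 0.09; 0.0173), at 8.47 in mutant 1 and between 7.72 and 7.81 in the others, and Tmem74, an autophagy regulator (fell by 0.23; 7.98 ± 0.07 and 8.21 ± 0.05; 0.0113).

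Other gene groups of the hippocampus were called by camera and lost the call with an estimated correlation. Subunits of oxidative phosphorylation had a median of -0.0856 with 7 of 39 above 0 (camera 0.0112, adjusted p = 0.623 with an estimated correlation), and cytosolic ribosomal proteins one of -0.0933 with 7 of 28 above 0 (camera 0.0297, adjusted p = 0.623 with an estimated correlation). Microglia and macrophage markers, such as C1qb (-0.20), Laptm5 (-0.18), Tmem119 (-0.16) and Aif1 (-0.13), had a median of -0.0899 with 1 of 17 above 0 (camera 0.0117, adjusted p = 0.538 with an estimated correlation). Postsynaptic density scaffolds, such as Dlgap1 (0.17), Dlg3 (0.17) and Grip1 (0.13), had a median of 0.0543 with 16 of 23 above 0 (camera 0.0297, adjusted p = 0.445 with an estimated correlation). Without wild-type array 4 the medians were 0.0029 for microglia (adjusted p = 0.385), -0.00928 for oxidative phosphorylation (0.944, with the camera direction turned), -0.0283 for ribosomal proteins (0.799) and 0.0109 for postsynaptic density genes (0.288). Without mutant 1 oxidative phosphorylation (0.0685), ribosomal proteins (0.0596) and postsynaptic density genes (0.144) also missed the threshold. So did ribosomal proteins without mutant 3 (0.0668) and postsynaptic density genes without mutant 4 (0.0537), whose median was 0.0917 without mutant 2. Adjusted over the list alone, 1 gene each passed in 4 lists with 0 past the test over all genes: Igfbp2 (0.63) of the meningeal and fibroblast markers, Calr (0.41) of the heat shock and unfolded protein genes, and Ppp1r1b (0.14), which stands in the striatal and the calcium lists.

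Over the whole hippocampus 51 genes passed, 47 higher and 4 lower, with 803 probes at an unadjusted p under 0.05 where chance gives 876. Without mutant array 1, 122 genes passed. Without mutants 2, 3 and 4 in turn, 2, 2 and 1 did, and without wild-type arrays 1, 2, 3 and 4 in turn, 7, 1, 2 and 12 did. Of the 24 fits without 1 array, only 8 left out a hippocampal array, and the losses are to be read against these 8. Clic6, Kl, Sostdc1, Folr1, Otx2, Cd59a and Lefty1 lost their call in 7 fits, Sulf1 and Fam171a1 in 6, Cldn2 and Slc4a2 in 5 and Tmem74 in 2. With the choroid plexus score as a covariate 1 gene passed, Srr. The score averages markers on the same arrays, many of them among the called genes, so the loss of their calls follows largely from how it is made. On the log2 intensity scale 39 passed, of which 36 are among the 51, and Kl, Sostdc1, Kcne2 and Lefty1 lost their call. The count was 2 from the 8 hippocampal arrays alone or without the trend in the prior variance, 10 with a robust prior and between 84 and 97 with other scalings or array weights. Without both animals numbered 3, Srr was the 1 gene that passed.

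As the mean over the 3 regions, Srr and Tmem74 fell in the mutants. Tmem74 fell by 0.14 ± 0.02 (SE, limma adjusted p = 0.0244). Genes next in order did not pass, among them Cd59a (0.58, adjusted p = 0.202), Ctsc, a lysosomal protease (0.15, 0.238), and Haus8, of the mitotic spindle (-0.14, 0.238). Nor did Col18a1, a basement membrane collagen (0.17, 0.432), Fut8 (0.07, 0.467), Llph (-0.14, 0.551), or the activity-induced genes Dusp1 (-0.40) and Npas4 (-0.28). Choroid plexus markers had a median of 0.282 (camera 3.12e-07, adjusted p = 0.39 with an estimated correlation), heat shock and unfolded protein genes -0.0559 and clock genes 0.0596, such as Dbp (0.32) (camera 0.0231 each, adjusted p = 0.39 with an estimated correlation). Immediate early genes had a median of -0.0254 and striatal neuron markers 0.0389 (camera 0.0053 and 0.0398, adjusted p = 0.522 with an estimated correlation for each). Without 1 array, immediate early genes had -0.0146 (cerebellar wild type 4 or frontal cortex wild type 2), and striatal markers 0.0244, 0.0251 and 0.0603 (frontal cortex mutant 4, wild type 2 and wild type 4). Clock genes had 0.0364 and 0.0353 (frontal cortex mutant 2 and hippocampal mutant 3). Adjusted over the list alone, 2 immediate early genes passed, Dusp1 and Npas4, with 0 over all genes. The count of 2 was 39 without hippocampal mutant 1. It was 1 without cerebellar mutant 3, cerebellar wild type 1 or 4, frontal cortex wild type 2 or 3, or hippocampal mutant 4 or wild type 4. Tmem74 lost its call in these 7 fits and in those without frontal cortex mutant 1 or 2, where the count stayed at 2 with another gene, so in 9 of 24 (adjusted p up to 0.0795). The count was also 1 with the values as deposited, with median scaling, cyclic loess or quantile scaling within a region, with no filter, without both animals numbered 3, and with the replicate number as a fixed block, where Tmem74 had -0.14 with an adjusted p of 0.199.

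The mutant effect differed between regions for 0 genes over all genes in limma, with 964 probes at an unadjusted p under 0.05 where chance gives 876 and a smallest adjusted p of 0.212. The 10 genes with the smallest p were Srr, Wipi2 (0.26 in the cerebellum, 0.00 in the frontal cortex and 0.01 in the hippocampus), H2bu2 (-0.09, 0.12 and -0.03), Cldn2 (-0.10, -0.01 and 0.98), Sulf1 (-0.12, -0.15 and 0.99), Slc31a1, a copper transporter (-0.06, -0.05 and 0.68), Lbp, a lipopolysaccharide-binding protein (-0.15, 0.03 and 0.68), Inmt (-0.08, 0.08 and 0.22), Prkcq (-0.10, -0.01 and 0.19) and F5, a coagulation factor (-0.07, -0.03 and 0.18). Without hippocampal mutant 1 the count was 84.

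**Figure D3:**
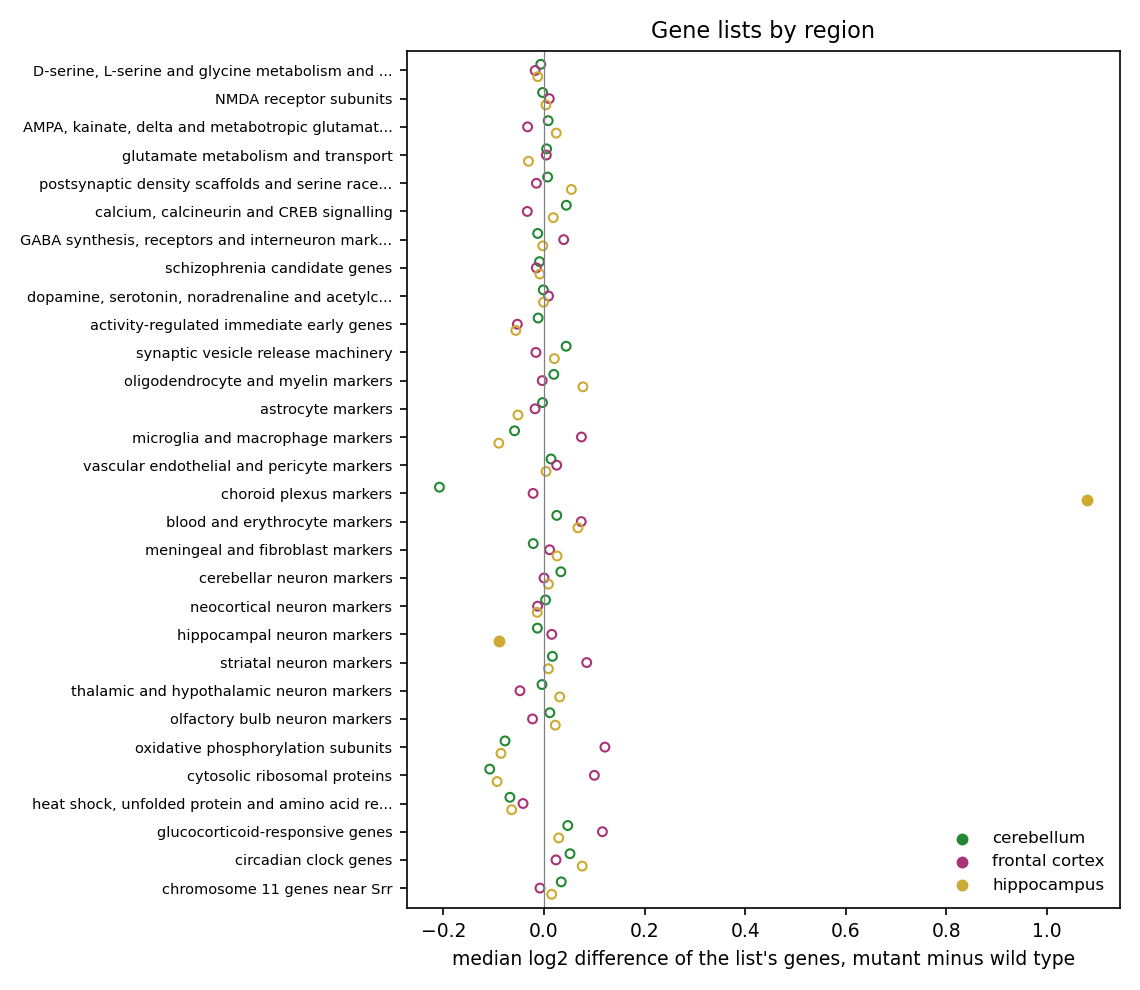
Median log2 difference between mutants and wild type for each of the 30 gene lists, with a point for each region and filled points where camera with an estimated correlation gave an adjusted p under 0.05. The choroid plexus markers in the hippocampus (1.08) stand farthest from 0.

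The other lists were not called in any region or for the mean, and are given as the median in the cerebellum, the frontal cortex and the hippocampus. Glutamate metabolism and transport had 0.00505, 0.00451 and -0.031, GABA genes -0.0127, 0.039 and -0.0025, and genes of the monoamine and acetylcholine systems -0.00146, 0.00901 and -0.00109. Schizophrenia candidate genes had -0.00906, -0.0153 and -0.00833, and Srr was the 1 member that passed in the frontal cortex and hippocampus, over all genes and adjusted over the list alone. Synaptic vesicle genes had 0.0439, -0.0162 and 0.0205. Among cell types, oligodendrocyte and myelin markers had 0.0194, -0.00365 and 0.0773 and astrocyte markers -0.00307, -0.0179 and -0.0519. Vascular markers had 0.0138, 0.0251 and 0.00396, blood markers 0.0253, 0.0739 and 0.0673, and meningeal markers -0.0215, 0.011 and 0.0259. Among regional neuron markers, those of the cerebellum had 0.0334, -0.000104 and 0.0087, of the neocortex 0.00297, -0.0129 and -0.0136, of the thalamus and hypothalamus -0.00411, -0.0479 and 0.0311, and of the olfactory bulb 0.0115, -0.0229 and 0.0223. Median and mean had opposite signs for glutamate metabolism in the cerebellum and frontal cortex, blood markers in the cerebellum, myelin and cerebellar markers in the frontal cortex, and GABA and monoamine genes in the hippocampus. Thalamic markers in the cerebellum had a median below 0 and a camera direction above it. For the mean of the regions, adjusted over the list alone and not over all genes, Hbb-bt (0.37) and Hbb-b2 (-0.22) of the blood markers and Slc6a13 (-0.15) of the meningeal markers passed.

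Between wild-type regions, the cerebellum stood apart from the frontal cortex by genes of its own neurons. Pcp2, a Purkinje cell protein, was higher by 5.45 (13.20 ± 0.07 and 7.75 ± 0.13, SD, n = 4, limma adjusted p = 1.38e-25), Cbln1, the cerebellin that joins parallel fibres to Purkinje cells, by 4.93, En2, a patterning factor of the hindbrain, by 4.07, Zic1, a granule cell factor, by 3.98 and Calb2, calretinin, by 3.48. Lower in the cerebellum were Stx1a, a SNARE of transmitter release (-4.15; 8.37 ± 0.18 and 12.52 ± 0.07; 3.54e-22), Nrgn, neurogranin (-4.05), Sst, somatostatin (-3.91), Enc1 (-3.80) and Hpcal4 (-3.74). All 11 cerebellar neuron markers were higher, with a median of 1.80 (camera 6.64e-11, adjusted p = 2.3e-05 with an estimated correlation). Striatal markers such as Rgs9 (-3.09) and Drd1 (-2.07) had a median of -1.14 (3.68e-09, adjusted p = 0.0267 with an estimated correlation), and 11 of 13 neocortical markers were lower, such as Mef2c (-2.74), Rprm (-2.41) and Tbr1 (-2.03), with a median of -0.936 (3.95e-07, adjusted p = 0.00383 with an estimated correlation). Of 23 postsynaptic density genes 18 were lower and 2 higher (median -0.599; 3.95e-07, adjusted p = 0.00871 with an estimated correlation). Microglia markers such as Laptm5 (-1.20) and Cx3cr1 (-0.69) had a median of -0.389 (0.00192, adjusted p = 0.202 with an estimated correlation). Medians were -0.199 for immediate early genes (2.89e-04, adjusted p = 0.285 with an estimated correlation) and -0.332 for synaptic vesicle genes (0.00783, adjusted p = 0.35 with an estimated correlation). In all, 7860 genes differed, 4214 higher and 3858 lower, of which 212 had probes both ways, beside the lower brightness of the cerebellar arrays. With the values as deposited 12084 differed, 445 higher and 11724 lower, with a median shift of all genes of -0.348.

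Against the hippocampus, the cerebellum was again higher in Pcp2 (at least 5.66, since its hippocampal level of 7.54 lay at the 10.2 percentile, adjusted p = 5.13e-26), Cbln1 (5.12), En2 (4.14), Zic1 (3.77) and Chn2, a Rac regulator (3.57). It was lower in Cpne6, a copine of hippocampal neurons (-4.75; 8.77 ± 0.21 and 13.52 ± 0.14, SD, n = 4; 5.17e-22), Enc1 (-3.95), Sst (-3.92), Camkv (-3.89) and Nrgn (-3.84). All 13 hippocampal neuron markers were lower, such as C1ql2, of mossy fibre synapses (-3.68), Fibcd1 (-3.53) and Spink8 (-3.06), with a median of -0.865 (camera 8.88e-12, adjusted p = 1.5e-05 with an estimated correlation). Postsynaptic density genes had a median of -0.577 (3.64e-06, adjusted p = 0.0156 with an estimated correlation) and neocortical markers one of -0.839 (8.13e-04, adjusted p = 0.0358 with an estimated correlation). Microglia markers had a median of -0.375 (0.00123, adjusted p = 0.3 with an estimated correlation) and immediate early genes one of -0.394 (0.0152, adjusted p = 0.646 with an estimated correlation). In all, 7555 genes differed, 3978 higher and 3778 lower, of which 201 had probes both ways, beside the same difference in brightness. With the values as deposited 11872 differed, 494 higher and 11456 lower, with a median shift of -0.29.

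Between the hippocampus and the frontal cortex, hippocampal markers were higher and striatal and neocortical markers lower. C1ql2 was higher by 3.09 (11.50 ± 0.20 and 8.41 ± 0.19, SD, n = 4, limma adjusted p = 4.07e-17), Fibcd1, an acetyl-binding membrane protein, by 2.76, Spink8 by 2.73, Crym, a thyroid hormone binding protein, by 1.71 and Serpina3n, a protease inhibitor of reactive glia, by 1.68. Lower were Scn4b, a sodium channel subunit (-2.35, adjusted p = 7.21e-15), Rgs9 (-2.25), Cckbr, the cholecystokinin receptor of the brain (-1.83), Myl4 (-1.81) and Krt12 (-1.71). Of 13 hippocampal neuron markers 12 were higher, and 13 adjusted over the list alone, with a median of 0.779 (camera 6.69e-37, adjusted p = 3.88e-09 with an estimated correlation). All 10 striatal markers were lower, such as Drd1 (-1.63), Ido1 (-1.37) and Ppp1r1b (-1.23), with a median of -1.31 (2.06e-35, adjusted p = 4.14e-05 with an estimated correlation). Neocortical markers had 7 lower and 2 higher, such as Mef2c (-1.51), Rprm (-0.93), Tbr1 (-0.83) and Otof (-0.62), with a median of -0.307 (1.52e-07, adjusted p = 0.00176 with an estimated correlation). Clock genes had a median of -0.188 (1.16e-04, adjusted p = 0.0687 with an estimated correlation), GABA genes -0.186 (0.00125, adjusted p = 0.0574 with an estimated correlation) and D-serine genes 0.0881 (0.024, adjusted p = 0.0572 with an estimated correlation). In all, 1437 genes differed, 669 higher and 769 lower. Of all genes, 6554 did with the values as deposited, 938 higher and 5686 lower, and 2811 with median scaling, 1897 higher and 918 lower.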

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

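Of the tests in this part, those of choroid plexus tissue, of an equal rise and of the Y-linked genes were chosen after the result was seen, while those of compression and of other splits were chosen before. A sample standing apart from the other 3 of its group is marked by chance in about 1 in 20 groups: 135 groups were looked at, 7 were expected and 17 found.

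Choroid plexus genes were higher in hippocampal mutants 2, 3 and 4 and not in mutant 1, which stood apart with a gap to the nearest mutant, as a share of the group's range, of 0.914 for the list score, 0.873 for Clic6, 0.965 for Sostdc1, 0.872 for Kcne2, 0.856 for Sulf1 and 0.943 for Slc4a2. These same values exclude a rise of equal size in every mutant, with no separate test: 3 of the 4 mutant scores exceeded the highest wild-type score (0.0807) and the other was -0.108. The mean of the 37 genes that rose in the hippocampus and are outside the marker list followed the choroid plexus score over the 8 cerebellar arrays, group means removed. There r was 0.983 (rho = 0.976, exact one-sided permutation p = 0.00521 and 0.00694, r = 0.963 without the 2 arrays farthest from the median). Over the 41 probes of these genes the median r was 0.884, with 39 above 0. In hippocampal mutant 1, with a score of -0.108, the mean of these genes was 8.144, above the highest wild type (8.121). These genes were picked for being higher in these mutants, mutant 1 included, than in these wild types. Their level in mutant 1 is therefore no separate sign of a rise there. The cerebellar values tie most of these genes to the markers but favour neither dissection nor a change of the choroid plexus in the mutants. Different amounts of choroid plexus tissue in the dissected samples may be a source. A change in the mutants that varies between animals may be one too, and both stay open. The score varied within wild-type cerebellum too (SD 0.599, against 0.0578 in wild-type hippocampus). Mutants numbered 2, 3 and 4 scored -0.325, 0.182 and -0.467 in the cerebellum (highest wild type 0.763). In the frontal cortex they scored 0.00388, -0.13 and -0.093 (highest wild type 0.105). The rise was thus not seen in same-numbered mutant arrays of other regions, which does not bear on a change limited to the hippocampus. The most abundant marker, Ttr, was at 14.96 in the 3 high mutants, the top of the scale, Ecrg4 (2.09, adjusted p = 0.0688) and Igf2 (0.88, 0.0951) had the same sign, and of the 14 markers, fixed as a list earlier, 7 lay above the median probe and 2 above the 75th percentile in wild-type hippocampus, with 0 in another list.

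The fall of Srr was smaller in the cerebellum than in the frontal cortex and than in the hippocampus (unadjusted values of limma's test 0.00144 and 5.65e-05). For the hippocampus, compression of dim values in the deposited table is argued against as the whole source. Mapped to bead intensity by quantiles and less background, the fall was still smaller in the cerebellum than in the hippocampus by 0.771 (SE 0.208). On that scale the differences were -0.497, -1.05 and -1.27 (SE 0.172, 0.205 and 0.117, n = 4 each) in the cerebellum, frontal cortex and hippocampus. The cerebellum was not tested against the frontal cortex on that scale. Background signal from another transcript on the 1 Srr probe, which may weigh more where Srr is low (8.63 in wild-type cerebellum), and a regional difference in the decay of the mutant transcript stay open, as untested.

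The Y-linked transcripts Eif2s3y and Kdm5d were near the array floor in arrays numbered 3 of both genotypes, though the labels call all mice male. Over the 3 regions Eif2s3y averaged 7.52 in mutant 3 and 9.58 in the other mutants, and 7.53 and 9.35 in wild type. Uty, also Y-linked, was dim in all mice and differed by -0.142 in mutants and -0.109 in wild type, with wild type 3 (7.70) above wild type 2 (7.67) in the cerebellum. A variant under the Eif2s3y probe is argued against, since another Y-linked gene, Kdm5d, was lower too, by at least the difference of -0.477 found in wild type. That mutant 3 is a female (XX) animal may account for its values, since Xist was higher than in the other mutants by at least 0.551 in every region. For wild type 3 that reading is argued against, as its lowest regional difference of Xist was -0.04 and the mean over regions -0.00878, and what sets its values apart stays open.

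Other splits of the 8 arrays of a region gave as many genes as the real one in 14 of 35 splits for the cerebellum (6 genes, highest other 1834), 7 of 35 for the frontal cortex (1 gene, highest other 54) and 3 of 35 for the hippocampus (51 genes, highest other 75), so that chance is not excluded for these counts. The hippocampal splits that gave as many (75 and 55) kept mutants 2, 3 and 4, the arrays high in choroid plexus genes, together with 1 wild type. For the mean it was 7 of 100 drawn splits (2 genes, highest other 957), so that chance is not excluded there either. These splits regrouped each region on its own. Same-numbered arrays, which may come from 1 animal, were not kept together. For the interaction the real count was 0, so that 100 of 100 splits reached it by construction (highest other 269) and nothing follows about chance. The cerebellar split with 1834 genes, which set mutant 1 with wild types 1, 2 and 4, points to a structure of the samples. Between wild-type regions chance is argued against, since only the real split, 1 of 35, gave as many genes, the smallest share possible. The cerebellum against the frontal cortex gave 7860 genes (highest other 2) and against the hippocampus 7555 (highest other 2504). The hippocampus against the frontal cortex gave 1437 (highest other 5). These splits cannot tell a region from a slide or processing step that its arrays may share.

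Single arrays standing apart in other genes were mutant 3 for Rbfox1 in the cerebellum (gap 1 of the range; 7.65 against 7.58), wild type 3 for H2bu2 (0.897) and Nrgn (0.902) in the frontal cortex, and, in the hippocampus, mutant 4 for Srr (0.971; 8.92 against 8.72 to 8.73), mutant 1 for Fam171a1 (0.881), wild type 1 for Pcp2 (0.909) and wild type 4 for En2 (0.915), Sst (0.86) and Myl4 (0.842). Wild type 4 stood apart for Serpina3n both in the hippocampus (0.946; 11.11 against 10.01 to 10.07) and in the frontal cortex (0.833; 9.19 against 8.38 to 8.51).

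The mutant effect on gene lists differed between regions by camera, adjusted over lists and pairs. Between the cerebellum and the frontal cortex, p was 7.67e-06 for oxidative phosphorylation, 0.000189 for ribosomal proteins, 0.00326 for microglia and 0.024 for calcium signalling. Between the frontal cortex and the hippocampus, it was 4.05e-23 for choroid plexus, 6.96e-07 for oxidative phosphorylation, 0.000161 for ribosomal proteins, 0.000604 for microglia, 0.01 for hippocampal neurons, 0.0193 for AMPA, kainate, delta and metabotropic receptors and 0.024 for calcium signalling. Between the cerebellum and the hippocampus, it was 6.41e-33 for choroid plexus and 0.024 for meningeal markers. With an estimated correlation 0 of these 13 differences passed, and the smallest adjusted p was 0.0697.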

How the results depend on the processing

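Of the tests here, those on the log2 intensity scale, on bead intensities as in the plan, with normexp, without both animals numbered 3 and with the choroid plexus score were chosen after the data were seen. Of 474 values of counts and Srr under alternatives, 403 stayed within bounds, 70 counts moved by over 1.5 times and 1 difference left the threshold; of 2866 values of single genes 272 left it, 24 passed it and 0 turned direction; of 638 list values 125 left it and 1 turned direction. Dim signal limits small differences, since values near background are compressed. Unless the setting itself says so (fewer arrays or probes, another threshold), the cause was not tested.

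Cerebellum (6 genes): 10 at an adjusted p of 0.1; 0 with a fold of at least 1.5, with median scaling, cyclic loess, scaling within a region, values as deposited, the 8 arrays alone or array weights (limma; 1760 probes at an unadjusted p under 0.05 in the reported fit); 3 with the stricter filter; 10 without animals numbered 3, of which 3 (Fut8, Rbfox1, Wipi2) are among the 6; 2 with the choroid plexus score; 1 on the log2 intensity scale and with each of the bead summaries (mean, median, mean of log2, normexp). Frontal cortex (1): 0 from the 8 arrays alone, where Srr was -0.70 with a limma adjusted p = 0.477. Hippocampus (51): 25 at 1.5-fold, 84 with median scaling, scaling within a region or values as deposited, 87 with cyclic loess, 21 with the stricter filter, 2 from the 8 arrays alone, 2 without trend, 10 with a robust prior, 97 with array weights, 39 on the log2 intensity scale with 36 of the 51 kept, 1 without animals 3 and 1 with the choroid plexus score. Mean (2): 1 at 1.5-fold, with median scaling, cyclic loess, scaling within a region, values as deposited, no filter, animals 3 left out, bead medians and mean of log2. Cerebellum against frontal cortex (7860): 1922 at 1.5-fold and 12084 as deposited. Cerebellum against hippocampus (7555): 1818 and 11872. Hippocampus against frontal cortex (1437): 250, 6554, 2811 with median scaling (1897 higher, 918 lower) and 2415 with array weights; values as deposited shifted the median of all genes by -0.348, -0.29 and -0.0775.

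Leaving out 1 array gave 4 to 43 genes in the cerebellum (43 without mutant 1, 34 without wild type 3, 16 without mutant 4; Svep1 lost its call in 17 of 24 fits, Fcsk in 9), 1 to 2 in the frontal cortex (2 without mutant 1 or wild type 4), 1 to 122 in the hippocampus (122 without mutant 1, with all 51 genes among them; 2, 2 and 1 without mutants 2, 3 and 4; 7, 1, 2 and 12 without wild types 1 to 4), 1 to 39 for the mean (39 without hippocampal mutant 1; 1 without cerebellar mutant 3, wild type 1 or 4, frontal cortex wild type 2 or 3, hippocampal mutant 4 or wild type 4; Tmem74 lost its call in 9) and 0 to 84 for the interaction (84 without hippocampal mutant 1). Between regions it gave 7341 to 7996, 6994 to 7702 and 1139 to 1514 genes. Srr ranged from -0.26 to -0.17 in the cerebellum, -0.82 to -0.62 in the frontal cortex and -0.92 to -0.83 in the hippocampus, and kept its call in the last 2. The oxidative phosphorylation list in the hippocampus ranged from -0.122 to -0.00928 and turned in camera direction without wild type 4 (adjusted p = 0.944), and the microglia list ranged from -0.115 to 0.0029 (0.385, without wild type 4). Other camera calls were lost without some 1 array. In the frontal cortex these were glucocorticoid (mutant 2, wild types 1, 2 and 4, cerebellar mutant 3, wild types 3 and 4), immediate early and microglia (mutant 4, wild type 2), striatal (mutants 2 and 4, wild type 2), calcium (mutants 3 and 4, wild types 2 and 4) and glutamate receptor genes (11 arrays). In the hippocampus they were oxidative phosphorylation (also mutant 1), ribosomal proteins (mutants 1 and 3, wild type 4) and postsynaptic density genes (mutants 1 and 4, wild type 4). In the cerebellum they were ribosomal proteins and oxidative phosphorylation (mutants 2 and 3, wild types 1, 2 and 4) and choroid plexus (mutants 1, 2 and 4, wild types 2 and 4), and for the mean immediate early (1 array), clock (5), heat shock (8) and striatal genes (11). The choroid plexus and hippocampal neuron calls of camera at the preset correlation of 0.01 held in the hippocampus without each array. The estimated correlation and fry were not rerun without an array.

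Same-numbered arrays of the 2 genotypes correlated at -0.274 to 0.415 (mean 0.11) over 12 pairs, 8 of them over 0.1. All 4 pairs passed 0.1 in the frontal cortex, where the block left Srr the 1 called gene (limma adjusted p = 0.0313) and ended the list call of glucocorticoid-responsive genes (0.0562) and no other. Not all did in the cerebellum and the hippocampus. With the replicate number within a region as a fixed block, 3 genes passed in the cerebellum, 1 in the frontal cortex, 44 in the hippocampus, 1 for the mean (Tmem74 at an adjusted p of 0.199) and 0 for the interaction. A different block, genotype and number as 1 animal across regions, taken as random (correlation 0.0176), gave 6, 1, 51, 2 and 0.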

Other observations

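All tests in this part were chosen after the result was seen.

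Across the 3 regions, genes that respond to glucocorticoids were alike in arrays of 1 genotype and number and differed between numbers. Sgk1, a kinase induced by corticosterone, was at 12.66, 12.25 and 12.57 in the cerebellum, frontal cortex and hippocampus of mutant 2. The score of the glucocorticoid list, relative to its genotype and region, was 0.288 in mutant 2, against -0.0754, -0.0803 and -0.132 in mutants 1, 3 and 4, and 0.132 in wild type 3, and differed between numbers with a permutation p of 4e-04 (adjusted over the 30 lists 0.006). Immediate early genes differed too (permutation p = 3e-05, adjusted 9e-04), with 0.134 in mutant 2 and 0.122 in wild type 2 against -0.149 in mutant 4 and -0.116 in wild type 4. Heat shock genes (adjusted p = 0.0079), clock genes (0.01) and the D-serine list (0.016) did as well. Single genes with such differences included Tmem87a and Rmdn3, both on chromosome 2, Lcn2, an acute phase protein, Tsc22d3, a glucocorticoid-induced leucine zipper protein, and Slc2a1, the glucose transporter of brain vessels.

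The number may mark 1 animal sampled in all 3 regions: 86 probes of 82 genes had an effect of the number within genotype past an adjusted p of 0.05, against at most 9 in 100 shuffles of the numbers within groups, where the median was 0. Eif2s3y, Xist and Kdm5d, which set arrays numbered 3 apart, are among them. Over all tested probes the likeness was weak. Arrays of 1 genotype and number correlated between regions at -0.309 to 0.482 (mean 0.0888) over 24 pairs, 11 of them over 0.1. Same-numbered arrays of the 2 genotypes within a region had a mean of 0.11. The like signs in both genotypes for numbers 2 and 4, for immediate early genes and for blood markers (0.113 and 0.0803 for number 2, -0.198 and -0.177 for number 4), leave open that the number also marks a day or batch shared by a mutant and a wild type. The blood list did not pass the permutation test over the lists (adjusted p = 0.1). For number 2, signs were unlike for glucocorticoid (0.288 and -0.058), heat shock (0.0674 and -0.0489) and clock genes (0.106 and -0.00811). For number 4 they were unlike for clock genes (-0.09 and 0.0558) and alike for the other lists just named. The D-serine list had like signs for each number (0.028 and 0.0203, -0.0234 and -0.0153, -0.00977 and -0.0214, 0.00519 and 0.0163), as had blood markers. Immediate early genes had unlike signs for number 1 (0.0471 and -0.0307) and number 3 (-0.032 and 0.0244). Differences in hormone level or in handling stay open too, as untested.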
